A study of Mus musculus with 24 samples.

How the data were processed

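Livers of 24 male UM-HET3 mice, a genetically mixed stock made by crossing inbred lines, were profiled by CEL-seq, a method that barcodes polyadenylated RNA and sequences the 3′ end of each transcript. Per the submitters' processing notes, reads were handled with bcl2fastq 1.8.4, Trimmomatic 0.32, STAR 2.5.2b and featureCounts 1.5 on the mouse build mm10. The annotation release, the strand setting and the use of molecular identifiers are not given in the sources used here. The deposited values are read counts per Ensembl gene, whole numbers with no normalization, with 1 column per library and 0 columns unused. If reads were not collapsed by molecular identifier, counts include amplification copies. Without a stated strand setting, reads of overlapping or antisense genes cannot be told apart.

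The table held 43629 genes, of which 42462 identifiers matched a symbol in the reference name table. Identifiers without a symbol held 0.0671% of the reads. Gene types and positions came from GENCODE gene models on GRCm38, the assembly also called mm10. Total counts per library ranged from 1047933 to 3865563, with a median of 2489256, and 25481 genes had a count in at least 1 library.

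Groups were taken from the library titles and compound labels. The design text describes the animals of each group as biological replicates. No pair of libraries within a group was a duplicate: the chi-square statistic per degree of freedom ranged from 3.92 to 34.4 over genes with at least 10 counts. In all 24 libraries the Y-linked gene Ddx3y was detected and Xist was near 0, in accord with the male label.

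Genes were filtered with edgeR's filterByExpr over the 5 groups, which left 9716 genes, and libraries were scaled by TMM. The main test was edgeR 4.0.16 (R 4.3.3), a quasi-likelihood test with robust dispersion, in 1 model over all 24 libraries with control as reference and 19 residual degrees of freedom. The biological coefficient of variation was 19.7%. Each compound was compared with control, AZD8055 with KU-0063794, the mean of the 4 compounds with control, and all 5 groups together. P-values were two-sided and adjusted by Benjamini-Hochberg over the genes tested, with a threshold of 0.05. Values per library are log2 CPM with a prior count of 2. Intervals are 95%.

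Before the data were examined, 50 gene lists (pathways, complexes and cell type markers) were fixed, and the 43 with at least 5 tested members were tested with limma 3.58.1 camera at a preset inter-gene correlation of 0.01, adjusted over the lists of each comparison. Camera asks whether the members rank apart from the other genes. The same lists were tested with camera's estimated correlation, with fry, and by permuting the list mean per library, exactly or with 100000 draws for the mean of 4 compounds. The model and these lists were fixed before the data were examined, as was the rule for naming genes. Where fewer than 10 genes passed, the rule named the 10 with the smallest p in each comparison, and for each list that passed it named up to 4 members with the smallest p. Predicted gene models were not named.

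A clock score was defined after the data were seen, as the mean log2 CPM of 6 genes (Per1, Per2, Per3, Ciart, Tef, Usp2) minus that of 4 genes (Arntl, Clock, Npas2, Nfil3). The structural RNA share was the percentage of counts in small nuclear, nucleolar, ribosomal and similar RNA genes, also defined after the data were seen. Its log2 was used in correlations and as a covariate.

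The procedure was tested on simulated counts for the 9716 genes with 200 genes changed. Each gene was drawn independently, in a single run per comparison, without the variation that genes share between livers. The shares recovered describe such counts. Of the genes changed 2-fold, the test recovered 65.7% for ascorbyl-palmitate, 61.2% for AZD8055, 74.6% for KU-0063794 and 62.7% for rilmenidine, 47.8% for AZD8055 against KU-0063794 and 89.6% for the mean of 4 compounds. At 1.5-fold the matching shares were 26.9%, 26.9%, 31.3%, 34.3%, 13.4% and 61.2%.

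Other analyses fixed in advance used RLE factors, library size only, no low-count filter, a filter of 5 CPM in at least 4 libraries, the replicate number as a block, only the 2 groups compared, DESeq2 1.42.0, limma-voom with sample quality weights, and each library left out in turn. Added after the data were seen were the clock score and the structural RNA share as covariates, leaving out 3 libraries of late clock phase, leaving out control replicates 6 and 7, and the permutation of list means. These 2 controls had the lowest TMM factors of all libraries. Correlations of fold changes between compounds were set beside 20 simulations of unchanged groups that shared the same controls.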

Results

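Liver gene expression was measured in 24 male mice at 4 months of age, 1 month after diets with 1 of 4 compounds were started at 3 months. The compounds were ascorbyl-palmitate, a fat-soluble ester of vitamin C, at 6.3 ppm, the mTOR kinase inhibitors AZD8055 at 20 ppm and KU-0063794 at 10 ppm, and rilmenidine, an imidazoline receptor agonist used against high blood pressure, at 10 ppm. Each compound had 4 libraries and the control diet had 8. The series title describes these as compounds with a predicted effect on lifespan, and the comparisons ask how the liver responded to each. Total counts per library ranged from 1047933 to 3865563, and 9716 genes were tested.

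No gene passed the edgeR threshold in any comparison, and the number with an unadjusted p under 0.05 is given below beside the 485.8 that chance gives. The biology is therefore described by gene lists fixed beforehand, and single genes are given as values that did not pass. Lists also passed the camera test in random regroupings of the same livers. The median number passing there was 6 for ascorbyl-palmitate (real groups 3), 5 for AZD8055 (5), 6 for KU-0063794 (5) and 6 for rilmenidine (8). It was 1 for AZD8055 against KU-0063794 (2) and 5 for the mean of 4 compounds (10). A passing list thus ranks apart in these animals without being tied to the diet by that test alone.

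Ascorbyl-palmitate livers had lower expression of chaperone genes. All 17 tested members of the heat shock list lay below control, with a mean log2 fold change of -0.59, and the list fell as a set (camera adjusted p = 1.5e-11). The adjusted p was 0.061 with an estimated correlation and 0.012 with fry. With adjustment over the list alone, 9 members were lower and 0 higher, against 0 over all genes tested. Among them were the cytosolic chaperone Hsp90ab1 at -0.50 ± 0.10 (log2 fold change ± SE), the inducible chaperone Hspa1b at -1.98 ± 0.47, the small heat shock protein gene Hspb1 at -0.89 ± 0.24 and Hsph1 at -1.20 ± 0.36. All 4 treated libraries lay below the control mean for each of these genes. Hspa1b has a near-identical copy, Hspa1a, so the split of reads between the pair is uncertain. The list mean per library was 5.09 ± 0.11 log2 CPM (SD, n = 4) against 5.63 ± 0.35 in control (n = 8), a difference of -0.54 with an interval of -0.86 to -0.21 (exact permutation p = 0.0141, 0.285 after adjustment over the lists). Hsp90ab1 (ENSMUSG00000023944) lies on chromosome 17 from 45567775 to 45573271 and Hspa1b (ENSMUSG00000090877) on chromosome 17 from 34956436 to 34959238 in mm10.

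The ATF4 and unfolded protein response list also fell as a set with ascorbyl-palmitate (20 of 26 members below control, camera adjusted p = 5.4e-05). It joins chaperone genes of the endoplasmic reticulum with ATF4 targets such as Sesn2 and Trib3, and is called the unfolded protein response list for short. The adjusted p was 0.397 with an estimated correlation. Adjusted over the list alone, 10 members were lower, among them the luminal chaperone Hspa5 at -0.72 ± 0.22, Sdf2l1 at -0.81 ± 0.24, Creld2 at -1.20 ± 0.37 and the disulfide isomerase Pdia3 at -0.64 ± 0.21. Ribosome biogenesis genes fell as a set too (28 of 34 members below control, mean -0.18, adjusted p = 0.0103), with an adjusted p of 0.407 with an estimated correlation and 0.0983 without ascorbyl-palmitate replicate 3, where the mean was -0.14. Its leading members were Nolc1 at -0.68 ± 0.23 and Gnl3 at -0.62 ± 0.24, and 0 members passed over the list alone. The other genes with the smallest p were the lipogenic transcription factor Srebf1 at 0.61 ± 0.14, the insulin receptor substrate Irs2 at -1.70 ± 0.43, Calu at -0.55 ± 0.12, Etfbkmt at -0.90 ± 0.21, Tmem33 at -0.37 ± 0.09, Hyal1 at -0.62 ± 0.16, Creld1 at -0.56 ± 0.14 and the caspase-8 regulator Cflar at -0.60 ± 0.15. With edgeR 0 genes passed (smallest adjusted p = 0.138, Hsp90ab1) and 701 had an unadjusted p under 0.05. DESeq2 called 3 genes, Hsp90ab1, Hspa1b and Cdkn1a, and limma-voom 0. The clock score of these livers was -0.17 ± 2.55 (SD, n = 4) against -2.05 ± 0.86 in control (n = 8, exact permutation p = 0.0465, 0.139 after adjustment over 12 tests), and replicate 1 alone stood at 3.59.

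With AZD8055 the ATF4 and unfolded protein response list fell as a set and the cholesterol synthesis list rose as a set. In the first list 22 of 26 members lay below control, with a mean of -0.33 (camera adjusted p = 3.4e-05, and 0.604 with an estimated correlation). Sdf2l1 was at -0.83 ± 0.24, Creld2 at -1.02 ± 0.36, Pdia6 at -0.31 ± 0.12 and Dnajb9 at -0.64 ± 0.25, and 0 members passed over the list alone. Of the 25 genes of the cholesterol synthesis list 16 lay above control, with a mean of 0.13 (adjusted p = 0.00959, and 0.989 with an estimated correlation). Besides synthesis enzymes the list holds genes of sterol uptake and regulation. Over that list alone 2 genes were higher, Pcsk9, whose product directs the LDL receptor to degradation, at 0.48 ± 0.10, and the sterol regulator Srebf2 at 0.50 ± 0.14. Neither encodes a synthesis enzyme. The enzyme genes Msmo1 at 0.37 ± 0.13 and Fdft1 at 0.31 ± 0.14 did not pass over the list alone (edgeR p adjusted over the list = 0.0537 and 0.212). Interferon response genes fell as a set (30 of 34 below control, mean -0.33, adjusted p = 0.00191, and 0.958 with an estimated correlation), led by Iigp1 at -0.34 ± 0.12 and Oasl1 at -0.87 ± 0.35. Heat shock genes fell as a set (17 of 17 below control, mean -0.29, adjusted p = 0.012, and 0.958 with an estimated correlation), with Chordc1 at -0.51 ± 0.17. So did nuclear genes of oxidative phosphorylation (58 of 76, mean -0.05, adjusted p = 0.0322, and 0.989 with an estimated correlation), with Ndufb2 at -0.33 ± 0.11, although its second member by p, Cox7a2l, was at 0.25 ± 0.09. The cholesterol, interferon, heat shock and oxidative phosphorylation calls were each lost without AZD8055 replicate 1 (adjusted p = 0.0694, 0.0855, 0.0694 and 0.0694), although the heat shock mean itself moved further from 0, to -0.38. With each of 12 libraries left out in turn, these calls were lost in 2, 1, 4 and 7 fits, and the unfolded protein response call in 0. The cholesterol mean was 0.08 without control replicate 2 and 0.22 without control replicate 6, and the oxidative phosphorylation mean -0.03 without control replicate 7. The oxidative phosphorylation call was also lost with library size alone and with the structural RNA covariate, and both it and the heat shock call without the 3 livers of late clock phase or without control replicates 6 and 7.

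Of single genes under AZD8055, the retinol saturase gene Retsat came nearest to the threshold, at 0.64 ± 0.12 (edgeR adjusted p = 0.0557), with 8.72 ± 0.36 log2 CPM (SD, n = 4) against 8.11 ± 0.19 in control (n = 8) and all 4 livers above the control mean. Retsat (ENSMUSG00000056666) lies on chromosome 6 from 72598475 to 72608425. The plasma carrier Ttr was at -0.50 ± 0.10, the methionine cycle enzyme Bhmt at -0.64 ± 0.13, the acute phase protein gene Orm1 at -0.52 ± 0.11, Ythdc2 at 1.47 ± 0.33, Derl2 at -0.41 ± 0.10, Zcchc24 at 0.38 ± 0.09, S100a10 at -0.44 ± 0.10 and Fam25c at -0.79 ± 0.20. With edgeR 0 genes passed and 541 had an unadjusted p under 0.05. DESeq2 called 5 genes (Retsat, Ttr, Bhmt, Orm1, Pcsk9) and limma-voom 4 (Orm1, Pcsk9, Retsat, Ttr). Retsat passed in edgeR with library size alone (adjusted p = 0.0379) and without the 3 libraries of late clock phase, which include AZD8055 replicate 3 (adjusted p = 0.0178). It was at 0.43 without AZD8055 replicate 1 (adjusted p = 0.783), and the adjusted p was 0.277 with only the 2 groups in the model.

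KU-0063794 livers had lower acute phase genes, which encode plasma proteins of the inflammatory response. Of 28 members 25 lay below control, with a mean of -0.29 (camera adjusted p = 4.9e-06). This was the only list in any comparison that also passed with an estimated correlation (adjusted p = 0.0264), and the fry adjusted p was 0.00656. Over the list alone 5 members were lower, among them Orm1 at -0.38 ± 0.11, the fibrinogen chains Fgb at -0.27 ± 0.09 and Fgg at -0.27 ± 0.10, and serum amyloid Saa1 at -1.16 ± 0.37. Saa1 has close copies, so its count is uncertain, and it was at -0.74 without control replicate 7. The list mean per library was 7.50 ± 0.10 log2 CPM (SD, n = 4) against 7.71 ± 0.13 (n = 8), a difference of -0.21 with an interval of -0.37 to -0.05 (exact permutation p = 0.0141, 0.217 after adjustment over the lists). Hepatocyte marker genes, which share Fgb with this list, lay below control in 9 of 9 members (mean -0.20, camera adjusted p = 0.0304, and 0.453 with an estimated correlation), with Ttr at -0.23 ± 0.10 and Alb at -0.23 ± 0.11, a call lost in 5 of 12 fits with 1 library left out, with the clock covariate and without control replicates 6 and 7. Erythrocyte markers fell as a set, with 6 of 6 members below control and 0 past the threshold over the list alone (mean -0.56, adjusted p = 0.00235, and 0.453 with an estimated correlation), led by the globin genes Hba-a1 at -0.74 ± 0.32 and Hbb-bt at -0.69 ± 0.30, whose copies share sequence.

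Heat shock genes fell as a set with KU-0063794, with 15 of 17 members below control (mean -0.43, camera adjusted p = 7.5e-07, and 0.202 with an estimated correlation). Over the list alone 5 members were lower, among them Hsp90ab1 at -0.45 ± 0.10, Dnajb1 at -0.71 ± 0.22, Hspa1b at -1.37 ± 0.44 and Hsp90aa1 at -0.996 ± 0.34. The ATF4 and unfolded protein response list fell as a set (20 of 26, mean -0.15, adjusted p = 0.0384, and 0.532 with an estimated correlation), although its leading members lay on both sides, with the stress-induced genes Sesn2 at 0.87 ± 0.29 and Trib3 at 1.27 ± 0.50 above control and the chaperones Dnajb11 at -0.30 ± 0.12 and Hsp90b1 at -0.43 ± 0.17 below it. That call was lost in 5 of 12 fits with 1 library left out (adjusted p up to 0.1), with the clock covariate and without control replicates 6 and 7, and the mean was -0.10 without control replicate 2. The other genes with the smallest p were Tbc1d10a at 1.16 ± 0.28, Atoh8 at 0.88 ± 0.22, the liver-secreted Fgl1 at -0.59 ± 0.15, Zbtb21 at -1.29 ± 0.34, Rpp30 at 0.77 ± 0.21, the phosphoinositide 3-kinase subunit Pik3r2 at 0.73 ± 0.20, Cyp2d40 at -0.48 ± 0.13, Wipf3 at 1.01 ± 0.27 and the fatty acid transporter Slc27a2 at 0.35 ± 0.10. With edgeR 0 genes passed (smallest adjusted p = 0.795) and 581 had an unadjusted p under 0.05, and DESeq2 and limma-voom each called 0. The clock score was -0.53 ± 0.45 (SD, n = 4) against -2.05 ± 0.86 in control (n = 8, exact permutation p = 0.0121, 0.0727 after adjustment over 12 tests).

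Rilmenidine livers had lower cholesterol synthesis genes as a set (21 of 25 below control, mean -0.27, camera adjusted p = 1.6e-07, and 0.556 with an estimated correlation). Over the list alone 3 were lower, the sterol reductase Dhcr7 at -0.63 ± 0.17, the lanosterol demethylase Cyp51 at -0.43 ± 0.12 and Fdps at -0.49 ± 0.16. Without control replicate 6 the list mean was -0.18, and it kept its call. Nuclear genes of oxidative phosphorylation fell as a set by a small amount (70 of 76, mean -0.10, adjusted p = 8e-08, and 0.559 with an estimated correlation), with Ndufv1 at -0.20 ± 0.09 and Cox6b1 at -0.19 ± 0.09. Cytosolic ribosomal protein genes fell as a set (52 of 65 below control, mean -0.16, adjusted p = 0.00121, and 0.591 with an estimated correlation), with Rps4x at -0.27 ± 0.14, and this call was lost without rilmenidine replicate 3 (mean -0.10, adjusted p = 0.505). Rps4x was at -0.16 without rilmenidine replicate 2. Ribosomal protein genes have many processed pseudogenes, so their counts are uncertain. The GH-IGF1 axis list fell (14 of 17, mean -0.30, adjusted p = 0.0282, and 0.325 with an estimated correlation). Among its members were Igfbp1 at -1.74 ± 0.60, the growth hormone feedback gene Socs2 at -1.42 ± 0.50 and Irs2 at -0.98 ± 0.37. The list mean was -0.46 without rilmenidine replicate 3. This list joins hormone, receptor, binding protein and feedback genes, so its mean is not a measure of signalling through the axis. Apolipoprotein genes (16 of 20, mean -0.11, adjusted p = 0.0377, and 0.556 with an estimated correlation) fell as a set, with Apoh at -0.24 ± 0.10, as did hepatic stellate cell markers (9 of 12, mean -0.21, adjusted p = 0.0231, and 0.556 with an estimated correlation), with Colec11 at -0.50 ± 0.19, Ecm1 at -0.41 ± 0.18 and Dcn at -0.31 ± 0.13. With 1 of 12 libraries left out, the apolipoprotein call was lost in 7 fits and the GH-IGF1 and stellate calls in 3 each. The list means in these fits were -0.144 to -0.0922, -0.456 to -0.230 and -0.250 to -0.173 in that order. Without rilmenidine replicate 3, Ecm1 was at -0.24 and Dcn at -0.20. With the clock score as a covariate the apolipoprotein, stellate, GH-IGF1 and clock calls were lost. Without control replicates 6 and 7 the ribosomal protein, apolipoprotein, stellate and clock calls were lost, and without the 3 late-phase livers the apolipoprotein, GH-IGF1 and clock calls. The clock list shares genes with the clock score, by which the late-phase livers were also picked. Loss of its call with the covariate or without those livers was thus no separate check.

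The circadian clock list rose as a set with rilmenidine (13 of 19 above control, mean 0.54, camera adjusted p = 0.026, and 0.556 with an estimated correlation). It mixes genes of opposed phase, so its mean is not a level of the clock as a whole. Its first member by p, Nfil3, which enters the clock score with a minus sign, was at -1.15 ± 0.33. Hlf was at 0.45 ± 0.17, Cry2 at 0.61 ± 0.23 and Bhlhe40 at 0.92 ± 0.36. Without rilmenidine replicate 1 the mean was 0.23, Hlf was at 0.24 and the call was lost (adjusted p = 0.113). The clock score was -0.13 ± 1.70 (SD, n = 4) against -2.05 ± 0.86 in control (n = 8, exact permutation p = 0.0121, 0.0727 after adjustment over 12 tests). Rilmenidine replicate 1 alone stood at 2.29. The ATF4 and unfolded protein response list rose (18 of 26, mean 0.12, adjusted p = 0.0377, and 0.591 with an estimated correlation), with Creld2 at 0.72 ± 0.32, Manf at 0.56 ± 0.25 and Sel1l at 0.24 ± 0.11, while its member with the smallest p, the hepatokine Fgf21, was at -1.50 ± 0.64. That call was lost in 6 of 12 fits with 1 library left out, and the list mean was 0.03 without rilmenidine replicate 2 (adjusted p = 0.488), with Creld2 at 0.44 and Manf at 0.23. Sel1l was at 0.37 without rilmenidine replicate 1 and 0.15 without replicate 4. The other genes with the smallest p were N4bp2l1 at 0.85 ± 0.21, Cables2 at 0.43 ± 0.12, Afap1l1 at -0.98 ± 0.28, the matrix protein gene Sparc at -0.43 ± 0.12, Banp at -1.07 ± 0.31, Ripk2 at 1.03 ± 0.30, Zyx at 0.55 ± 0.16 and Tmem131l at 0.63 ± 0.19. With edgeR 0 genes passed (smallest adjusted p = 0.736) and 453 had an unadjusted p under 0.05, and DESeq2 and limma-voom each called 0.

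**Figure D1:**
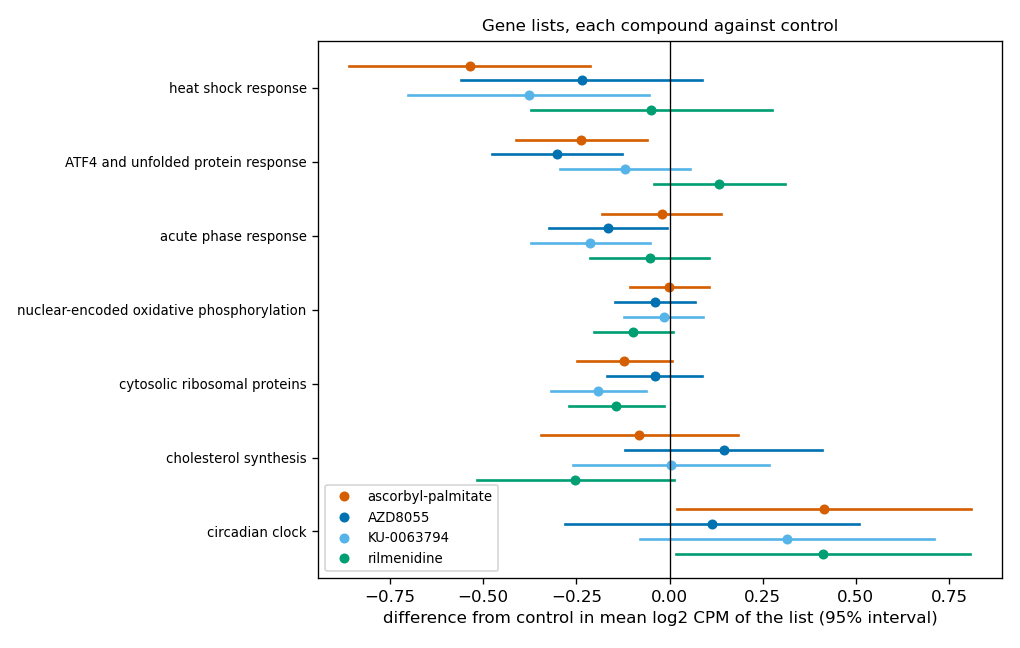
Difference from control in the mean log2 CPM of 7 gene lists for each compound (4 livers per compound, 8 controls), with points for the estimate and lines for its 95% interval. For heat shock genes the estimate is -0.54 with ascorbyl-palmitate, -0.24 with AZD8055, -0.38 with KU-0063794 and -0.05 with rilmenidine.

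**Figure D2:**
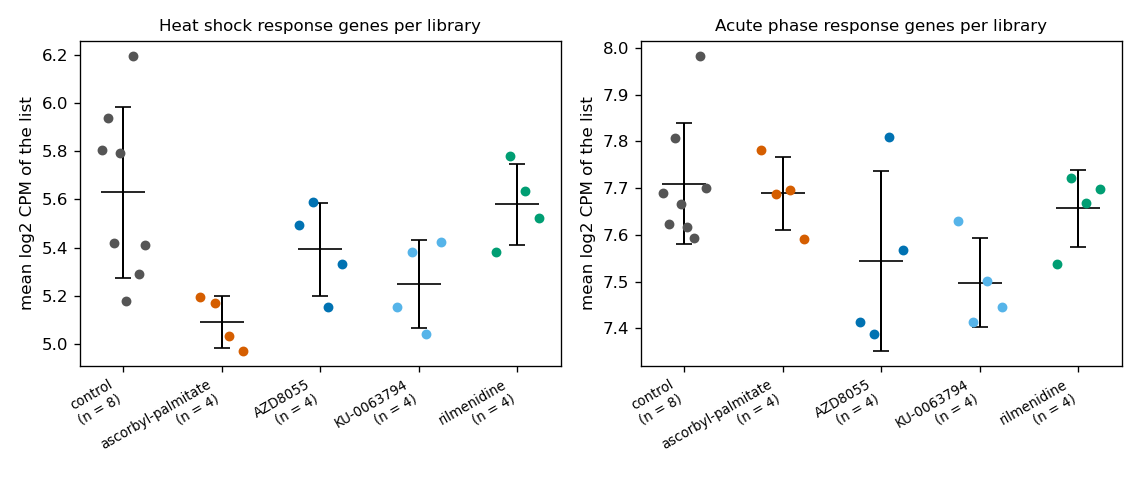
Mean log2 CPM of the heat shock and acute phase lists in each liver, by group, with the group mean and SD as bars. Heat shock means are 5.09 with ascorbyl-palmitate and 5.63 in control, and acute phase means are 7.50 with KU-0063794 and 7.71 in control.

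AZD8055 and KU-0063794 both inhibit mTOR kinase but were given at different doses, 20 and 10 ppm, so their difference is not one of compound alone. Against KU-0063794, the cholesterol synthesis list was higher as a set in AZD8055 livers (20 of 25, mean 0.15, camera adjusted p = 0.0478, and 0.704 with an estimated correlation). Among its members were the regulator Pcsk9 at 0.50 ± 0.12 and the enzyme gene Fdft1 at 0.42 ± 0.16. Interferon genes were lower as a set (29 of 34, mean -0.28, adjusted p = 0.00651, and 0.704 with an estimated correlation), with Oasl1 at -1.04 ± 0.39 and Ifi27l2a at -0.86 ± 0.40. With each of the 8 libraries left out in turn, the cholesterol call was lost in 6 fits (adjusted p up to 0.167) and the interferon call in 2 (up to 0.247, with a mean of -0.17 without KU-0063794 replicate 2 and -0.43 without replicate 4). The cholesterol call was also lost with either covariate. The difference in acute phase genes was 0.05 with an interval of -0.14 to 0.23, and in heat shock genes 0.14 with an interval of -0.23 to 0.52. Neither interval excludes 0, nor does it show that the compounds act alike. Genes with the smallest p were Fgl1 at 0.84 ± 0.18, haptoglobin Hp at 0.62 ± 0.14, Etnppl at 0.68 ± 0.17, Faim at -0.75 ± 0.19, Dtx4 at 1.02 ± 0.27, Pkp4 at 0.48 ± 0.13, Lmo4 at 0.62 ± 0.17, Maf1 at -0.61 ± 0.17 and Cib3 at -3.37 ± 0.89. With edgeR 0 genes passed (smallest adjusted p = 0.523) and 392 had an unadjusted p under 0.05, and DESeq2 and limma-voom each called 0.

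Over the mean of the 4 compounds, heat shock genes were lower as a set (17 of 17, mean -0.36, camera adjusted p = 1.3e-07, and 0.145 with an estimated correlation), with Hsp90ab1 at -0.30 ± 0.07 and Hspa1b at -1.31 ± 0.29, each below the control mean in 16 of 16 livers. Control livers varied in Hspa1b, with an SD of 1.00 log2 CPM (n = 8). With rilmenidine alone the heat shock list did not pass, and its difference from control was the smallest of the 4 compounds. Acute phase genes were lower (21 of 28, mean -0.15, adjusted p = 0.00148, and 0.145 with an estimated correlation), with Orm1 at -0.29 ± 0.08, Fgg at -0.23 ± 0.07 and Saa1 at -0.86 ± 0.25. The unfolded protein response (mean -0.15, adjusted p = 0.00592, and 0.47 with an estimated correlation), oxidative phosphorylation (-0.05, 0.012, and an adjusted p of 0.863 with an estimated correlation), cytosolic ribosomal protein (-0.14, 0.012, and an adjusted p of 0.806 with an estimated correlation) and ribosome biogenesis lists (-0.11, 0.0344, and an adjusted p of 0.47 with an estimated correlation) were lower too. So were hepatocyte (-0.13, 0.0486, and an adjusted p of 0.47 with an estimated correlation) and erythrocyte markers (-0.32, 0.0183, and an adjusted p of 0.656 with an estimated correlation). The clock list, which mixes genes of opposed phase, was higher as a set (13 of 19, mean 0.51, adjusted p = 0.012, and 0.22 with an estimated correlation), with Cry2 at 0.67 ± 0.17, Hlf at 0.41 ± 0.12 and Nfil3 at -0.85 ± 0.22. CAR and PXR targets, the drug-metabolism genes, were higher by 0.05 (adjusted p = 0.0489, and 0.47 with an estimated correlation), with Por at 0.43 ± 0.22, although the member with the smallest p, Aldh1a7, was at -0.20 ± 0.08. Por was at 0.25 without ascorbyl-palmitate replicate 1. The CAR and PXR mean ranged up to 0.10, without control replicate 3. It turned negative with the clock covariate (-0.0399) and without control replicates 6 and 7 (-0.00527). Without control replicate 7 Saa1 was at -0.44, and the mean was 0.00025 for CAR and PXR targets, -0.12 for erythrocyte markers, -0.09 for acute phase genes and -0.02 for oxidative phosphorylation. The clock mean was 0.33 without AZD8055 replicate 3, and the unfolded protein response mean -0.10 without control replicate 2. With each of 24 libraries left out in turn, the hepatocyte call was lost in 14 fits, CAR and PXR and ribosome biogenesis in 9 each, oxidative phosphorylation in 6, cytosolic ribosomal proteins in 5, erythrocyte markers in 3 and the clock in 1. In these fits the hepatocyte mean stayed between -0.146 and -0.0947 and the ribosome biogenesis mean between -0.126 and -0.0828. Without control replicates 6 and 7 only the heat shock list of these 10 passed, with a mean of -0.29. With the clock covariate the CAR and PXR, clock, hepatocyte and erythrocyte calls were lost, without the late-phase livers the first 3 of these, and with library size alone the CAR and PXR, hepatocyte and oxidative phosphorylation calls. Loss of the clock call with the covariate or without those livers was no separate check, since its list shares genes with the clock score.

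Single genes over the mean of 4 compounds included Banp at -1.13 ± 0.22, Fam25c at -0.55 ± 0.13, Tmem131l at 0.60 ± 0.14, Zfp467 at 0.32 ± 0.08, Socs2 at -1.44 ± 0.33, Dntt at -1.27 ± 0.30, Slc27a2 at 0.28 ± 0.07 and Retsat at 0.34 ± 0.08. With edgeR 0 genes passed (smallest adjusted p = 0.143) and 690 had an unadjusted p under 0.05. DESeq2 called 6 (Banp, Hspa1b, Socs2, Hsp90ab1, Dntt, Nfil3) and limma-voom 0. Across all 5 groups edgeR called 0 genes, with 524 at an unadjusted p under 0.05, DESeq2 18 and limma-voom 0.

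Fold changes against control were compared between compounds over 9716 genes, which are not independent replicates. The median correlation of the 6 pairs was 0.396, from 0.261 for ascorbyl-palmitate and AZD8055 to 0.495 for ascorbyl-palmitate and KU-0063794. Unchanged groups sharing the same controls gave 0.328 and 0.331 for these pairs in simulation. Each gene was drawn independently there, without the variation that genes share between livers. The simulated values are therefore no test of an excess. Without the 3 late-phase livers the median was 0.221, and without AZD8055 replicate 3 the lowest pair was at 0.0956. The simulation was not repeated for these smaller groups. The covariance for ascorbyl-palmitate and KU-0063794 was 0.0427 against 0.025 simulated, an excess of 0.0178, and for AZD8055 and KU-0063794 it was 0.0302 against 0.025, an excess of 0.00523. The excess was 0.00929 for ascorbyl-palmitate and rilmenidine and 0.00704 for KU-0063794 and rilmenidine, and the value was below the simulated one for ascorbyl-palmitate and AZD8055 (-0.00276) and for AZD8055 and rilmenidine (-0.000716). With controls 1 to 4 serving 1 compound and controls 5 to 8 the other, the median correlation was 0.0722, from -0.032 to 0.184. Fewer controls also make each fold change noisier, which by itself lowers a correlation. The covariance was then 0.0177 or 0.0200 for ascorbyl-palmitate and KU-0063794, by which controls served which compound. For ascorbyl-palmitate and AZD8055 it was 0.000524 or -0.00358. The late-phase livers were kept in this comparison.

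Clock genes separated 3 treated livers from the rest. Ascorbyl-palmitate replicate 1 had a clock score of 3.59, rilmenidine replicate 1 of 2.29 and AZD8055 replicate 3 of 1.801, and the others lay between -3.34 and -0.05. Over the 24 livers, the structural RNA share was 0.151% to 1.93% of counts. The first principal component (10.8% of variance) correlated with the log2 of that share (Pearson r = 0.898, permutation p = 1e-05, the smallest 100000 draws can give, and Spearman rho = 0.885, permutation p = 1e-05, each 4e-05 after adjustment over 4 relations). Without the 2 farthest livers r was 0.865. The clock score correlated with the second component (8.53% of variance, r = -0.687, permutation p = 0.00118 after adjustment) and with the first (r = -0.471, 0.0263 after adjustment). The log2 structural RNA share did not correlate with the second (r = -0.245, 0.249 after adjustment). The clock genes, and any structural RNA genes that passed the filter, were themselves among the genes of the components. Both measures were also defined after the data were seen. These correlations are therefore descriptive.

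**Figure D3:**
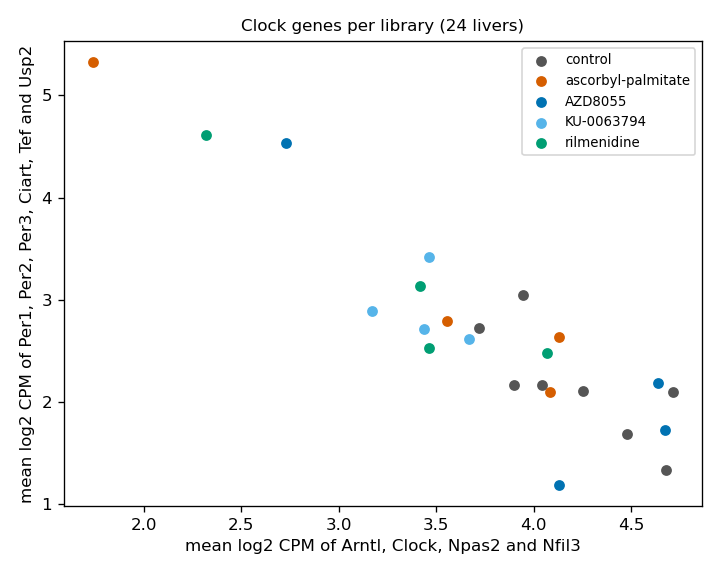
Mean log2 CPM of 6 evening-phase clock genes against that of 4 morning-phase clock genes in each of 24 livers, coloured by group. The 3 livers at the upper left have clock scores of 3.59, 2.29 and 1.801.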

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

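The tests of the clock phase, of the acute phase list and of calls made without a low-count filter were chosen after the results were seen. The heat shock pattern was itself taken from the results. Its tests used the clock score and the structural RNA share, which were also defined after the data were seen. Of 237 groups of values checked for a single value far from the others, 14 had one, near the 1 in 20 that chance gives.

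The clock score of AZD8055 replicate 3 was 1.801, against -2.45 for the next liver of its group. KU-0063794 replicate 1 had a structural RNA share of 1.59%, against 0.459% for the next. KU-0063794 replicate 4 had the lowest TMM factor of its group, 1.02, and the fewest genes detected, 13927. Erythrocyte markers were high in control replicate 7 at 7.87 log2 CPM, against 7.06 for the next liver. Stellate cell markers were low in AZD8055 replicate 2 at 4.50, and ribosome biogenesis genes in rilmenidine replicate 4 at 3.95. Socs2 was high in ascorbyl-palmitate replicate 4 at 7.07 and in AZD8055 replicate 4 at 6.56. In the AZD8055 group Bhmt reached 10.7 in replicate 4 and Slc27a2 10.5 in replicate 3. In control livers Derl2 reached 8.30 in replicate 6 and Pik3r2 3.31 in replicate 1. Zyx was at 4.92 in rilmenidine replicate 1.

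The clock scores of ascorbyl-palmitate 1, AZD8055 3 and rilmenidine 1 may reflect a later circadian phase at collection, for which no time of day is given. Greater depth of these libraries is argued against as a cause: with every library thinned to 1047933 counts, the lowest of the 3 scored 1.61 and the highest of the other 21 scored -0.229. A general loss of clock transcripts is argued against by the opposed arms, whose means correlated at r = -0.749 over the other 21 livers (permutation p = 0.00013). A phase of the animal, a different collection time and a diet effect stay open, and the design does not separate them. At equal depth these 3 livers had 13261 to 13687 genes detected, against 12276 to 13273 in the others, which was not explained.

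Lower heat shock genes over the mean of the 4 compounds kept most of their size under each technical test. With rilmenidine alone the heat shock list did not pass. The mean log2 fold change of -0.36 was -0.33 with the clock score in the model, -0.34 with the structural RNA share, -0.29 without control replicates 6 and 7, and no nearer to 0 than -0.27 with any 1 library left out. These values argue against a linear effect of the clock score or of structural RNA, and against a single liver, as the whole cause. The score is a single axis of phase, so genes that peak at other times could shift with phase without following it. Clock phase in that sense stays open. Handling of the livers at collection was not recorded and stays open, as does the diet, and 17 of 100 splits of the libraries, the real one included, gave as many passing lists as the 10 of this comparison (median of the others 5).

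Lower acute phase genes with KU-0063794 were at -0.29 with the clock score in the model. They were no nearer to 0 than -0.23 with any 1 of the 12 livers left out. These values argue against a linear effect of the clock score and a single liver as the whole cause. Clock phase off that axis stays open, as for the heat shock genes. Leaving out 1 liver cannot show a joint effect of several. Control replicates 6 and 7, for example, had the lowest TMM factors (0.924 and 0.909). A lower share of hepatocytes cannot be told apart: of the 4 other tissue cell types with a tested list, all lay above control, and the smallest adjusted exact permutation p was 0.531 (cholangiocyte markers). The criterion for that test was revised 2 times after its result was seen, first to adjust for the number of lists, and then to leave out erythrocyte markers, which lay below control (exact permutation p = 0.00404, or 0.0202 over 5 lists) but also follow the blood left in the tissue. With erythrocyte markers kept, either earlier criterion would have counted against a lower hepatocyte share.

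Other splits of the same libraries often gave as many calls as the real groups. The numbers of splits below include the real one. For genes, where the real count was 0, that held by definition in 100 of 100 splits (35 of 35 for AZD8055 against KU-0063794), and the highest other counts were 9 for ascorbyl-palmitate, 1 for AZD8055, 6 for KU-0063794, 6 for rilmenidine, 0 for AZD8055 against KU-0063794, 17 for the mean of 4 compounds and 2 for all 5 groups. For gene lists, as many passed in 91 of 100 splits for ascorbyl-palmitate (real 3, highest other 15), 62 for AZD8055 (5 and 15), 69 for KU-0063794 (5 and 18), 36 for rilmenidine (8 and 16), 17 of 35 for AZD8055 against KU-0063794 (2 and 6) and 17 of 100 for the mean of 4 compounds (10 and 14). Chance could not be excluded for any of these counts. Without a low-count filter as many genes were called in 11 of 60 splits for ascorbyl-palmitate (real 24, highest other 117), 9 of 60 for AZD8055 (25 and 164) and 8 of 60 for the mean of 4 compounds (32 and 132), so chance could not be excluded there either. Some splits gave several times the real count, which points to a structure of the samples or to the behaviour of low counts without a filter. In the real grouping most genes so called had also been in the filtered test (23 of 24 for ascorbyl-palmitate, 24 of 25 for AZD8055 and 26 of 32 for the mean, with median total counts of 1846.5, 3796 and 2239.5), so few low-count genes were among them. Which genes the other splits called was not recorded, so the cause stays open.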

How the results depend on the processing

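The clock and structural RNA covariates, the 2 sets of left-out libraries and the permutation of list means were chosen after the data were seen. Counts of genes stayed at 0 with RLE factors, the stricter filter and only the 2 groups compared. Library size alone gave 1 gene for AZD8055. No low-count filter gave 24 for ascorbyl-palmitate, 25 for AZD8055, 6 for KU-0063794, 3 for rilmenidine, 7 for AZD8055 against KU-0063794, 32 for the mean of 4 compounds and 88 across the 5 groups. DESeq2 gave 3, 5 and 6 for ascorbyl-palmitate, AZD8055 and the mean, and 18 across groups, and limma-voom gave 4 for AZD8055. The clock covariate gave 1 for AZD8055, and the structural RNA covariate 1 each for ascorbyl-palmitate and AZD8055. Without the 3 late-phase livers, AZD8055 had 2, AZD8055 against KU-0063794 1 and all groups 1. The cause of these moves was not tested.

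Of the lists, an estimated correlation left 0 for ascorbyl-palmitate, AZD8055, rilmenidine, AZD8055 against KU-0063794 and the mean, and 1 for KU-0063794. Fry left 1 for ascorbyl-palmitate, 1 for KU-0063794 and 0 for the others, and the permutation of list means left 0 in all 6. The smallest p that permutation could give was 0.00202 for 1 compound against control and 0.0286 for AZD8055 against KU-0063794. A single list at such a p cannot pass adjustment over 43 lists, so only the mean of 4 compounds was free of this limit. The clock covariate gave 4 for rilmenidine and 1 for AZD8055 against KU-0063794. The structural RNA covariate gave 9 for ascorbyl-palmitate, 8 for KU-0063794 and 1 for AZD8055 against KU-0063794. Without the late-phase livers ascorbyl-palmitate had 6 and AZD8055 3. Without control replicates 6 and 7 rilmenidine had 4 and the mean 1. The CAR and PXR list over the mean turned to -0.0399 with the clock covariate and -0.00527 without control replicates 6 and 7. The median correlation between compounds was 0.0722 with controls split and 0.221 without the late-phase livers. The cause was not tested.

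The replicate numbers were not taken to pair the samples. The rule asked that every same-numbered pair correlate over 0.1, which a weak shared factor would not meet. Of 40 such pairs 7 did (-0.214 to 0.232, median 0.021), against 18 of 184 pairs of other numbers (median -0.00539). Of 20 libraries, 10 correlated best with their own number among 4, a hint of a shared factor. The labels name littermate controls, without a litter per animal in the sample data used. A factor shared by number therefore stays open. With the replicate number as a block, ascorbyl-palmitate had 1 gene and the mean 4, ascorbyl-palmitate 9 lists, KU-0063794 9 and rilmenidine 3, and the median correlation was 0.503. Over the mean, Cyp3a11 turned to -0.0063, Alb to 0.0380 and the CAR and PXR list to -0.0762.

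With each library left out in turn, genes called ranged from 0 to 4 for AZD8055 (4 without control replicate 5), 0 to 2 for the mean (2 without control replicate 5) and 0 to 2 across groups (2 without rilmenidine replicate 1), and were 0 to 0 in the others. Lists ranged from 2 to 7 for ascorbyl-palmitate (7 without its replicate 1, and 6 without its replicate 2 or control 5). They ranged from 1 to 9 for AZD8055 (1 without its replicate 1, 9 without 2, 3 without 3 or control 6, 8 without control 4) and from 3 to 12 for KU-0063794 (3 without its replicate 1, 12 without 4, 9 without control 3, 8 without control 1, 2 or 5). They ranged from 5 to 11 for rilmenidine (5 without its replicate 3 or control 3) and from 0 to 4 for AZD8055 against KU-0063794 (0 without AZD8055 1 or KU-0063794 2, 4 without KU-0063794 4). For the mean they ranged from 3 to 12 (3 without control 7, 4 without rilmenidine 3, 5 without KU-0063794 1). The median correlation ranged from 0.27 without rilmenidine 1 to 0.447, and was 0.31 without AZD8055 3. The heat shock list kept its call in each of these fits for ascorbyl-palmitate, KU-0063794 and the mean, as did the acute phase list for KU-0063794. At this depth and number of livers, changes of 1.5-fold were recovered in 34.3% or less of simulated genes for a single compound. Detection at that size was thus partial in simulation, where genes were drawn independently, and smaller changes were not simulated.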

Other observations

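Autophagy, mTOR pathway, adrenergic and vitamin C lists did not pass for the compounds named here. For AZD8055 the mean log2 CPM of autophagy and lysosome genes differed from control by -0.02 (interval -0.11 to 0.07) and that of mTOR pathway genes by 0.01 (-0.06 to 0.08), with camera adjusted p of 0.658 and 0.996. For KU-0063794 these differences were 0.02 (-0.06 to 0.11) and -0.04 (-0.11 to 0.04), with adjusted p of 0.839 and 0.826. Cytosolic ribosomal protein genes were at -0.19 with KU-0063794 (interval -0.32 to -0.06, camera adjusted p = 0.052, which missed the threshold) and -0.04 with AZD8055 (-0.17 to 0.09). With rilmenidine the adrenergic and cAMP list differed by 0.03 (-0.20 to 0.25, adjusted p = 0.914), and with ascorbyl-palmitate the vitamin C list by -0.01 (-0.15 to 0.13, adjusted p = 0.981).

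Markers of Kupffer cells differed from control by 0.12 with ascorbyl-palmitate (interval -0.08 to 0.33), -0.03 with AZD8055 (-0.24 to 0.17), 0.13 with KU-0063794 (-0.08 to 0.34) and -0.02 with rilmenidine (-0.23 to 0.19). Sinusoidal endothelial markers differed by 0.04, -0.03, 0.02 and -0.04 in the same order. None of these 8 differences passed.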
